A study of Mus musculus with 12 samples.

How the data were processed

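Total RNA was extracted with Trizol from dissected maxillary prominences, and libraries were made from 2 µg of RNA by poly-T selection with an NEBNext Ultra kit, which does not mark strand, per the labels' protocols. Tissue came from 7 littermates, and the protocol does not say whether that number is per library or shared by the 3 libraries of a stage. The labels call the libraries independent RNA samples and biological replicates but do not say that they came from separate litters, so p-values measure the spread between these libraries. E14.5 is described in a separate block, and the title of its replicate 1 names 2 parts, which were used here as 1 library. Per the submitters' processing notes, FastQC, STAR 2.7.3a, HTSeq 0.12.4 and the mm10 build were used, without role or order, and the annotation release, strand setting and filters are not given in the sources used here.

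The deposited files hold whole-number counts per Ensembl gene, not normalized, for 53801 genes in each library, followed by 5 closing entries for alignments that no gene received. Those entries were kept out of library sizes and tests and made up 14.3% to 18.6% of listed alignments, of which alignments outside annotated genes were 1.92% to 6.21%, ambiguous ones 6.31% to 6.90% and multiply mapped ones 4.51% to 6.50%. Symbols and mm10 coordinates came from the GENCODE mouse release for the same assembly, in which 53620 of the identifiers matched and 181 did not, and 26 tested genes had no symbol. Depth was 28.3e6 to 33.9e6 counts in genes, with 22633 to 26914 genes seen per library. Reads carry no molecular identifiers, so intervals and floors cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom was at least 4.46 within a stage.

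Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 (18365 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per stage was fitted to all 12 libraries, which leaves 8 residual degrees of freedom and a shared estimate of the spread (biological coefficient of variation 0.142). The 5 contrasts and a joint test of any difference among the 4 stages were made, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes rising or falling at every step, or with a peak or trough, passed in each consecutive step concerned. Another scaling (size factors of DESeq2) moved the median log2 fold change of all genes by at most 0.025. Lists of genes fixed before the data were examined (32, for the cell types and pathways of this tissue and for tissues that a dissection could bring along) were tested with camera in limma 3.58.1 with an estimated inter-gene correlation and adjusted over 160 tests. Of the 88 list calls made with the preset correlation of 0.01, 78 were lost with the estimated one.

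Named genes were chosen by a rule written before the data were examined. At each of the 3 steps it took up to 8 genes with the largest rise and 8 with the largest fall among named genes with adjusted p under 0.05, a mean of at least 5 CPM in the higher stage and no overlap between the libraries of the stages. From each described list it took up to 4 called members with the largest change, and it took 6 genes per direction of the every-step classes and 5 per peak or trough class. Not every gene the rule picked is named in the text. Genes named outside it, after their values were seen, are Malat1, Neat1 and the follow-up markers of the closing section. Folds against a stage without counts are lower bounds from a floor of 3 counts over the stage, and with 1 to 3 counts the ratio is given with its 95% exact interval.

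The fit was tested on simulated data for E11.5 against E10.5, drawn for 18365 genes of which 18073 entered the test, with 200 changed. It recovered 41.8% of genes changed 1.5-fold, 62.7% at 2-fold and 84.8% at 4-fold, and 5.26% of its calls were false. Fewer genes were changed there than the real comparison called (4615). The adjusted threshold depends on that number, so these recovery rates do not carry over to the real comparisons. Alternatives were other scaling, filters and tests (limma-voom, DESeq2 1.42.0), the compared stages alone, globin and mitochondrial genes left out, a minimum change of 2-fold, replicate number as a block, each library left out in turn, and other set tests. Added after the data were seen were the share of alignments outside genes and the Y-linked level as covariates, E10.5 represented by replicate 3 alone, a stricter cut for libraries of 1 sex, a set test of marker lists with an estimated correlation, and a likelihood ratio test in DESeq2 for the joint comparison.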

Results

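Polyadenylated RNA was sequenced from the maxillary prominence of C57BL/6 mouse embryos. This facial swelling, filled mostly by mesenchyme of neural crest origin under a surface epithelium, gives rise to the upper jaw and the palatal shelves. Tissue was taken at embryonic day (E) 10.5, E11.5, E12.5 and E14.5, with 3 libraries at each stage and 12 in all. The labels call the libraries of a stage biological replicates. The series title names the developmental course of this tissue and its regulation as the subject. Each stage was compared with the stage before it, and E12.5 and E14.5 also with E10.5. Libraries held 28.3e6 to 33.9e6 counts in genes, and 18365 genes were tested. The first principal component held 63.7% of the variance and placed the stages in order of age. E10.5 libraries lay at -95.6 to -69.5, E11.5 at -67.5 to -58.1, E12.5 at 9.3 to 34.0 and E14.5 at 121.4 to 125.0. Correlation of log2 CPM was 0.981 to 0.992 between libraries of the same stage and 0.880 to 0.978 between stages. The share of alignments outside annotated genes was 2.16% to 2.42% at E11.5, 5.03% to 5.43% at E12.5 and 5.78% to 6.21% at E14.5. At E10.5 it was 2.67%, 1.92% and 4.88% in replicates 1, 2 and 3. Within E10.5, E12.5 and E14.5, libraries with a larger share also stood higher on the first component, while those of E11.5 did not. E10.5 replicate 3, at -69.5, lay nearest to E11.5, so that component cannot be read as age alone. Xist, the transcript that silences an X chromosome in female cells, measured 0.0739 CPM in E10.5 replicate 2 and 9.38 CPM in E12.5 replicate 2, against 209 to 2115 CPM in the other 10 libraries. The 4 Y-linked genes had no count in E14.5 replicate 1. Levels below are mean CPM (counts scaled to 1e6 per library) ± SD over 3 libraries.

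**Figure D1:**
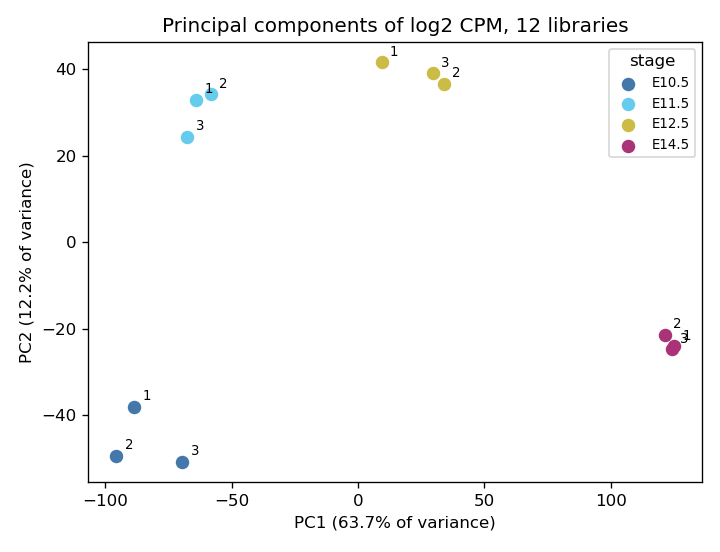
Scores of the 12 libraries on the first principal component (horizontal axis, 63.7% of variance) and the second (vertical axis, 12.2% of variance) of log2 CPM. Each point is a library, coloured by stage and numbered by replicate, and the stages follow the first component in order of age.

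**Figure D2:**
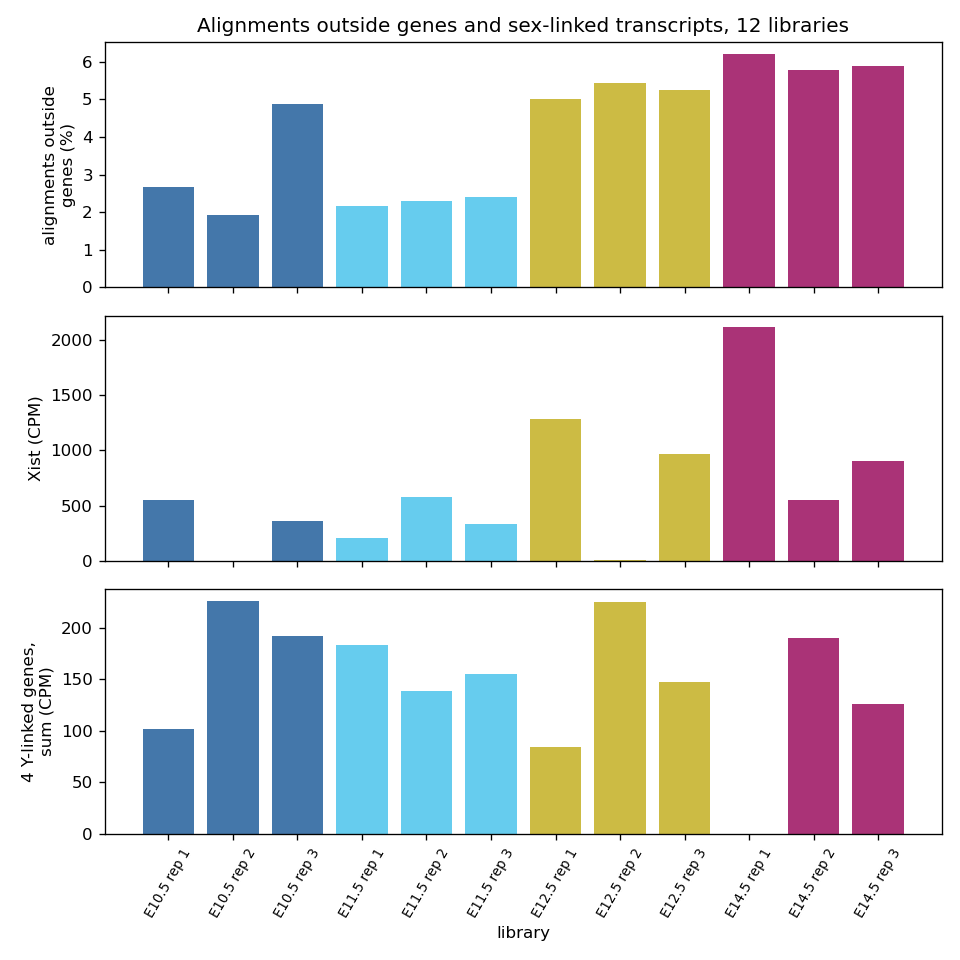
Bars give, for each of the 12 libraries, the percentage of alignments outside annotated genes (top), Xist in CPM (middle) and the summed CPM of 4 Y-linked genes (bottom), with bars coloured by stage. E10.5 replicate 3 sits at 4.88% in the top panel, near the E12.5 libraries, and E14.5 replicate 1 has no Y-linked count.

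From E10.5 to E11.5, genes of an early embryonic growth programme around Lin28 fell while interstitial matrix genes and regulators of palate development rose. Lin28a, an RNA-binding protein that blocks maturation of let-7 microRNAs, fell by 4.51 on the log2 scale (SE 0.21, adjusted p = 5.83e-08), from 56.6 ± 12.1 to 2.49 ± 0.24 CPM. Lin28b fell from 130.6 ± 10.8 to 22.3 ± 2.8 CPM, Trim71 from 64.2 ± 2.0 to 13.1 ± 2.2 CPM and Sall4 from 43.7 ± 7.1 to 8.95 ± 2.32 CPM. Osr2, a zinc finger factor needed for growth of the palatal shelves, rose from 6.82 ± 1.26 to 69.8 ± 14.0 CPM (log2 fold change 3.36, SE 0.16, adjusted p = 6.36e-08). Inhba rose from 1.08 ± 0.48 to 17.7 ± 4.3 CPM, Meox2 from 1.17 ± 0.10 to 7.99 ± 1.53 CPM and Shox2 from 15.8 ± 3.5 to 54.2 ± 5.8 CPM. Among matrix genes, the proteoglycan lumican (Lum) rose from 16.9 ± 1.0 to 143.2 ± 31.9 CPM. Ogn rose from 0.823 ± 0.371 to 32.6 ± 15.8 CPM and Tnc from 6.00 ± 4.57 to 55.9 ± 8.6 CPM. In numbers, 13 of the 16 tested genes of the Lin28 programme were lower and 1 higher. Of the others, 25 of 29 matrix genes were higher and none lower, and 16 of 21 palate regulators were higher and 1 lower. Adjusted over the list alone, these counts were 14 and 1, 27 and 0, and 17 and 1. Each of these lists passed the set test that compares a list with all other genes (adjusted p = 0.0370 with an estimated correlation, over 160 list tests).

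Of 22 neuronal genes, 17 were lower at E11.5 and none higher, also when adjusted over the list alone. Among them were Pou4f1, a homeobox factor of sensory neurons (29.1 ± 10.5 to 1.24 ± 1.25 CPM), Neurog1 (12.3 ± 3.9 to 0.588 ± 0.717 CPM) and the neuronal RNA-binding protein Elavl3 (20.7 ± 9.98 to 1.07 ± 0.96 CPM). The list as a whole did not pass (adjusted p = 0.350 with an estimated correlation). Endothelial genes were lower in 12 of 22 cases and higher in none (15 and 0 adjusted over the list alone), as for the VEGF receptor Kdr (66.6 ± 18.3 to 33.1 ± 5.6 CPM). Of the cartilage genes, 7 of 21 were lower, as for Sox9 (93.3 ± 11.7 to 33.2 ± 3.6 CPM). These lists gave adjusted p = 0.403 and 0.383 with an estimated correlation. Of 23 Wnt targets and inhibitors, a list that also holds ligands such as Wnt5a and Wnt11, 16 were higher and 2 lower (list adjusted p = 0.0646). The list is therefore no direct measure of the output of the pathway. Higher genes included Lef1 (35.0 ± 7.2 to 195.0 ± 22.1 CPM) and the Wnt inhibitors Apcdd1 (56.1 ± 21.2 to 362.3 ± 24.8 CPM) and Dkk1 (9.43 ± 3.71 to 48.7 ± 4.6 CPM). Of 21 osteoblast and bone matrix genes 9 were higher and 3 lower (list adjusted p = 0.203), and Ibsp fell from 2.53 ± 0.26 to 0.116 ± 0.056 CPM. Runx2, the factor that commits cells to the osteoblast lineage, rose from 4.62 ± 2.58 to 71.8 ± 8.2 CPM, and Col1a1 from 34.9 ± 6.9 to 257.1 ± 28.6 CPM. Basal keratins rose as well, Krt5 from 3.91 ± 1.99 to 123.6 ± 26.3 CPM and Krt14 from 26.1 ± 6.7 to 171.1 ± 45.8 CPM. In the basal epithelial list of 24 genes, 11 were higher and 4 lower (list adjusted p = 0.574).

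The largest rises at this step included Cbln4, a secreted synaptic organiser with 3 counts over all E10.5 libraries and 715 at E11.5 (ratio 237, 95% exact interval 80.9 to 1153). Others were Pde1a (0.161 ± 0.064 to 14.9 ± 6.2 CPM), Tnn (0.139 ± 0.213 to 7.73 ± 1.02 CPM) and the paired-box factor Pax1 (ENSMUSG00000037034, mm10 chromosome 2, 147361925 to 147393295), from 1.31 ± 0.87 to 66.2 ± 20.3 CPM. The largest falls included Sst (22.6 ± 7.9 to 0.676 ± 0.438 CPM), Grm2 (8.35 ± 3.88 to 0.217 ± 0.186 CPM) and Igdcc3. This immunoglobulin superfamily gene on chromosome 9 (65141189 to 65185872) went from 276.6 ± 39.9 to 11.8 ± 3.0 CPM (log2 fold change -4.55, SE 0.17, adjusted p = 7.16e-09). In total 2238 genes were higher and 2377 lower, 904 and 732 of them at least 2-fold. Without E10.5 replicate 3, which leaves only libraries with 1.92% to 2.67% of alignments outside genes, 2016 were higher and 2004 lower. Without E11.5 replicate 1 or 2 the lower genes numbered 1551 or 1486. With replicate number as a block the 3 list calls were lost (adjusted p = 0.0615 to 0.0857), and they also ended without E10.5 replicate 2 (adjusted p = 0.0561 for each), E10.5 replicate 3 (0.0775), E11.5 replicate 1 (0.0523) or E11.5 replicate 2 (0.0510).

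From E11.5 to E12.5, most muscle, cartilage and endothelial genes were higher and most genes of cell division were lower. The list of Wnt targets and inhibitors moved both ways. None of these lists passed with an estimated correlation (adjusted p = 0.123 to 0.381). Of 27 skeletal muscle genes 26 were higher and none lower. Among them were Acta1, the actin of skeletal muscle fibres (0.742 ± 0.145 to 13.5 ± 7.6 CPM), and Myh7 (0.299 ± 0.106 to 3.79 ± 1.46 CPM). Cartilage genes were higher in 15 of 21 cases and lower in none (16 and 0 adjusted over the list alone). The proteoglycan aggrecan (Acan) stood at 0.0691 ± 0.0340 and 4.17 ± 1.86 CPM, Cnmd at 0.242 ± 0.157 and 8.97 ± 1.70 CPM, and the matrilin Matn4 at 0.255 ± 0.268 and 18.7 ± 7.8 CPM. Of 22 endothelial genes 21 were higher and 1, Esm1, lower, as for endoglin (Eng, 13.2 ± 0.9 to 34.4 ± 7.0 CPM). Of 25 genes of the G2 and M phases 24 were lower, as for Top2a, the topoisomerase that untangles replicated chromosomes (1455 ± 67 to 726.5 ± 111.6 CPM, log2 fold change -1.002, SE 0.123, adjusted p = 5.15e-05). Of 25 DNA replication genes 23 were lower, as for the sliding clamp Pcna (750 ± 47 to 335.6 ± 71.7 CPM).

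Several Wnt targets and inhibitors that had risen at the earlier step fell. Lef1 went from 195.0 ± 22.1 to 12.8 ± 0.6 CPM (log2 fold change -3.93, SE 0.145, adjusted p = 9.03e-09). Dkk1 went from 48.7 ± 4.6 to 6.13 ± 1.21 CPM, Nkd1 from 132.0 ± 5.9 to 24.7 ± 5.1 CPM and Apcdd1 from 362.3 ± 24.8 to 70.4 ± 22 CPM. Over the list 12 of 23 were lower and 8 higher. The Wnt ligands Wnt9b (chromosome 11, 103727364 to 103749821) and Wnt3 (103774150 to 103817957), neighbours on the chromosome, fell together, from 71.0 ± 6.9 to 2.43 ± 1.23 CPM and from 30.8 ± 2.4 to 1.44 ± 0.58 CPM. Lix1 fell from 145.1 ± 10.3 to 8.32 ± 0.52 CPM and the homeobox gene Lmx1b from 15.3 ± 1.1 to 0.657 ± 0.626 CPM. Palate regulators were higher in 14 of 21 cases and lower in 3. At E12.5 Meox2 stood at 48.3 ± 5.2, Foxf2 at 77.2 ± 21.04 and Foxe1 at 36.5 ± 6.3 CPM, against 7.99 ± 1.53, 14.1 ± 3.9 and 7.95 ± 2.99 CPM. Matrix genes were higher in 18 of 29 cases and lower in none. Postn, an adhesive matrix protein, rose from 187.6 ± 28.3 to 851.3 ± 224.8 CPM. The Lin28 programme had 14 of 16 genes lower and none higher, with Lin28a at 0.222 ± 0.126 CPM.

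Genes of neurons and of brain, eye and olfactory tissue were higher at E12.5 in 11 of 22 and 12 of 17 cases, and lower in 2 and 1. The forebrain and placode gene Otx2 rose from 0.933 ± 1.285 to 15.9 ± 12.6 CPM. The neuropeptide gene Cck had 1 count over E11.5 and 682 over E12.5 (ratio 594, 95% exact interval 106.3 to 23500). Dbh, the enzyme that makes noradrenaline, had 2 and 514 (ratio 224, interval 61.7 to 1854). Afp, a fetal plasma protein, had no count at E11.5 and measured 27.6, 1.16 and 0.378 CPM in E12.5 replicates 1, 2 and 3. Its mean, at least 272-fold higher against a floor of 3 counts over the stage, came mainly from replicate 1, and its call was lost with limma-voom. Hand2os1, also among the largest rises (2 counts to 843), lies against Hand2, and reads of the pair cannot be separated without strand.

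None of the 32 lists passed at this step with an estimated correlation, while 6 had an unadjusted p under 0.05. Of the 32, 18 passed with camera's preset correlation and 21 with fry, which asks only whether a list moves on balance 1 way. With an estimated correlation, adjusted p = 0.203 for muscle, for the G2 and M phases, for DNA replication and for matrix, 0.123 for cartilage and 0.381 for endothelium. Likewise, adjusted p = 0.373 for Wnt targets and inhibitors, 0.215 for palate regulators and 0.0871 for the Lin28 programme. For neurons it was 0.732, and for brain, eye and olfactory tissue 0.383. Over all genes 4968 were higher and 4079 lower, and of those that changed at least 2-fold 2772 were higher and 410 lower. Of the called noncoding genes, 785 were higher and 96 lower. The share of alignments outside genes rose at the same step, from 2.16% to 2.42% in the E11.5 libraries to 5.03% to 5.43% in those of E12.5. No comparison within libraries of like share was possible. With that share as a covariate, chosen after the data were seen, 407 genes were higher and 286 lower. This left 6 muscle, 4 cartilage, 4 matrix, 0 endothelial, 3 neuronal and 3 brain, eye and olfactory genes higher. It left 3 genes each of the G2 and M phases and of DNA replication and 9 of the Lin28 programme lower. Palate regulators were left at 9 higher and 2 lower, and Wnt targets and inhibitors at 5 higher and 8 lower.

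From E12.5 to E14.5, most bone matrix, muscle fibre and differentiated keratinocyte genes were higher and most jaw patterning factors lower, and of these lists only that of bone passed. Ibsp, the bone sialoprotein secreted by osteoblasts (ENSMUSG00000029306, mm10 chromosome 5, 104299171 to 104311469), rose from 0.318 ± 0.250 to 1506 ± 263 CPM (log2 fold change 12.17, SE 0.33, adjusted p = 1.53e-10). Of 21 osteoblast and bone matrix genes 20 were higher and 1 lower, also when adjusted over the list alone, and the list passed (adjusted p = 0.0162 with an estimated correlation, 0.0516 with replicate number as a block). They included Dmp1, a protein of mineralising matrix (0.0812 ± 0.0884 to 20.8 ± 7.8 CPM), and Mmp13 (0.0494 ± 0.0447 to 7.10 ± 1.74 CPM). All 27 tested muscle genes were higher, such as Myh8, a myosin heavy chain of developing fibres (9.91 ± 4.40 to 199.1 ± 31.3 CPM). Of the 19 suprabasal and periderm keratinocyte genes 18 were higher and none lower, such as Krt4 (0.0790 ± 0.0734 to 29.5 ± 7.8 CPM), Krt13 (0.0707 ± 0.0183 to 12.6 ± 3.0 CPM) and the desmosomal cadherin Dsg1a (0.467 ± 0.302 to 69.6 ± 28.7 CPM). Those lists gave adjusted p = 0.0769 and 0.0680 with an estimated correlation.

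Matrix genes were higher in 27 of 29 cases and lower in 1 (list adjusted p = 0.0769). Col1a1 rose from 484.6 ± 131.3 to 5698 ± 952 CPM and decorin (Dcn) from 31.6 ± 14.4 to 480.9 ± 47.2 CPM. In cartilage, 15 of 21 genes were higher and 2 lower (list adjusted p = 0.203), with Matn1 rising from 0.783 ± 0.470 to 26.7 ± 1.9 CPM. Leukocyte genes were higher in 18 of 22 cases (list adjusted p = 0.104), led by Cpa3, a mast cell protease (0.589 ± 0.215 to 58.7 ± 9.3 CPM). Melanocyte genes were higher in 7 of 8 (list adjusted p = 0.215), with Dct at 0.556 ± 0.080 and 9.20 ± 1.24 CPM and Pmel at 0.757 ± 0.114 and 9.34 ± 0.45 CPM. All 3 tested embryonic globins fell (list adjusted p = 0.0680). Hbb-bh1 fell from 122.7 ± 71.9 to 1.79 ± 0.81 CPM and Hba-x from 513.7 ± 212.8 to 23.3 ± 12.3 CPM. Of 25 jaw mesenchyme patterning factors 18 were lower and 3 higher (19 and 3 adjusted over the list alone, list adjusted p = 0.191), such as Barx1 (220.1 ± 20.2 to 68.0 ± 6.9 CPM) and Six2 (245.1 ± 23.1 to 61.4 ± 4.7 CPM). Palate regulators were lower in 13 of 21 cases and higher in 4 (15 and 4 adjusted over the list alone, list adjusted p = 0.229). Foxf2 fell from 77.2 ± 21.04 to 9.20 ± 2.22 CPM and Tbx22, a gene mutated in X-linked cleft palate, from 46.3 ± 10.3 to 6.22 ± 0.95 CPM.

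Besides Ibsp, the largest rises were genes without a count at E12.5. Against a floor of 3 counts over that stage, Pla2g2f was at least 514-fold higher, the mast cell tryptase Tpsb2 at least 415-fold. The hair follicle keratins Krt25 and Krt73 were at least 364-fold and 205-fold higher, and Lipi, Slc36a2 and Sdr16c6 at least 299-fold, 232-fold and 208-fold. Tpsb2 and Hba-x belong to families of similar genes, and their counts depend on how reads were shared among members. Sp8 fell from 10.7 ± 8.2 to 0.391 ± 0.165 CPM. In all 4233 genes were higher and 4413 lower, 2033 and 1036 of them at least 2-fold. All 6 libraries had over 5% of alignments outside genes. The labels describe E14.5 in a separate block of samples, so stage and any difference in handling cannot be told apart. The osteoblast list lost its call without E12.5 replicate 3 (adjusted p = 0.0513).

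**Figure D3:**
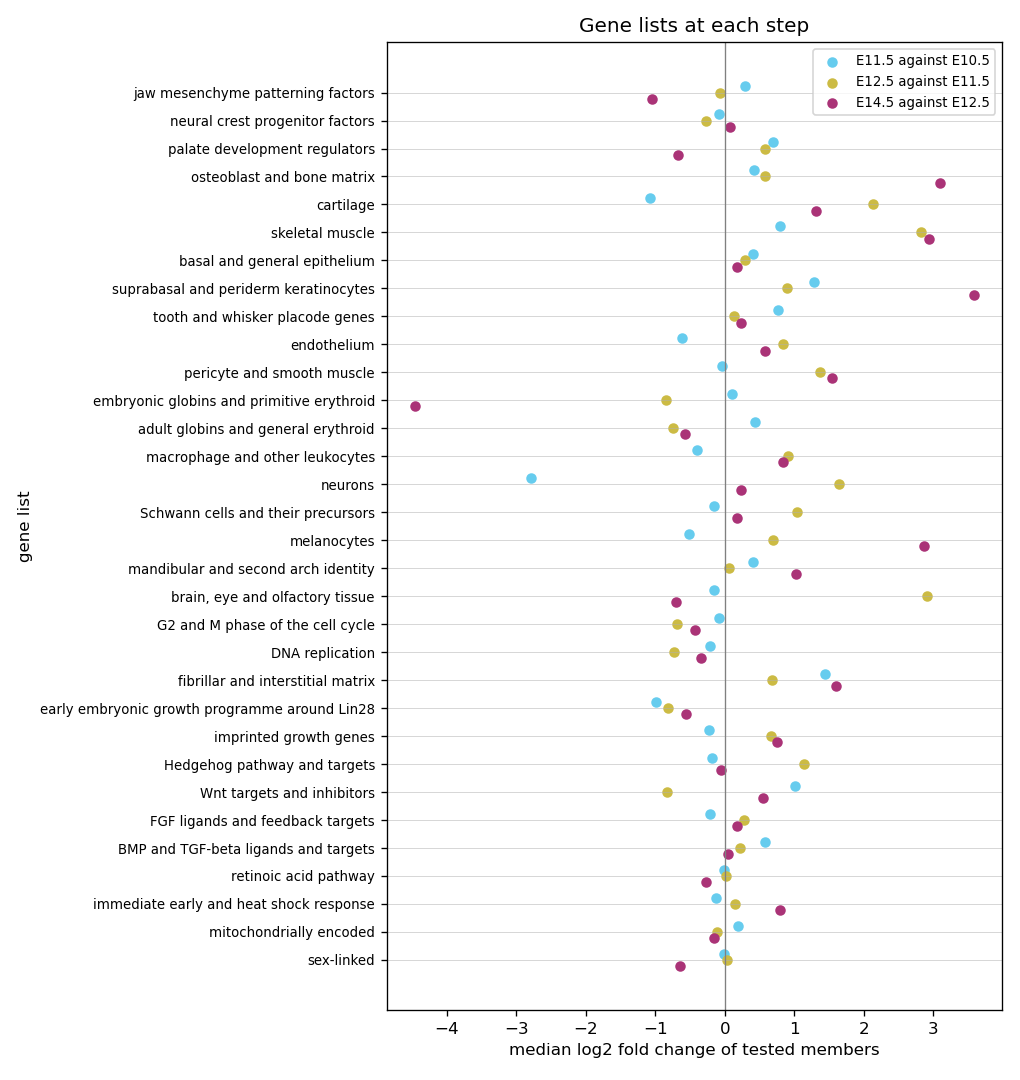
Median log2 fold change of the tested members of each of the 32 gene lists (vertical axis) at each of the 3 steps between stages, with 1 coloured point per step. The osteoblast list stands at 3.09 from E12.5 to E14.5 and the Lin28 programme is below 0 at every step.

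Over the whole course, 14995 of 18365 genes differed among the 4 stages (81.7%). Of these, 320 rose and 254 fell at every step. Leaving out 1 library brought the falling genes to as few as 137, and the share of alignments outside genes as a covariate left 54 rising and 29 falling. Among those that rose at every step, Agtr2, an angiotensin receptor of fetal mesenchyme, went from 0.219 ± 0.062 CPM at E10.5 to 410.5 ± 56.5 CPM at E14.5. The proteoglycan Aspn, whose first step was lost with limma-voom, rose from 0.0911 ± 0.0665 to 161.2 ± 22.3 CPM, and Mymk, the myoblast fusion protein, from 1 count to 2351 (ratio 1971, 95% exact interval 353 to 77890). S100a14, the desmosomal Dsg1b and the muscle gene Smpx had no count at E10.5 and were at least 1112-fold, 308-fold and 270-fold higher at E14.5 against a floor of 3 counts over the stage. Among those that fell at every step were Fgf8, a signal of the facial ectoderm (23.8 ± 4.7 to 0.0626 ± 0.0543 CPM), whose first step did not pass without E10.5 replicate 3 or E11.5 replicate 2. Others were Sall4 (43.7 ± 7.1 to 0.302 ± 0.182 CPM), Igdcc3 (276.6 ± 39.9 to 1.90 ± 0.23 CPM), Lin28b (130.6 ± 10.8 to 2.80 ± 0.58 CPM) and Trim71 (64.2 ± 2.0 to 1.43 ± 0.20 CPM). The chemokine Cxcl14 was among 512 genes with a peak at E11.5 (33.6 ± 18.5, 453.9 ± 107.2 and 34.4 ± 12.0 CPM from E10.5 to E12.5), as were Glis1, Gabrp and Avpr1a. Tlx2 and Srrm4 were among 788 genes with a trough at E11.5 (as few as 470 with 1 library left out). Otx2 was among 639 with a peak at E12.5, and Irx4 was among 555 with a trough at E12.5 (10.4 ± 1.0, 0.351 ± 0.110 and 13.4 ± 1.7 CPM from E11.5 to E14.5). The covariate left 93 and 102 genes with a peak or trough at E11.5, and 78 and 100 at E12.5. Independent lists of the same sizes would give 139.5 genes rising and 126.9 falling at every step. They would give 497 and 643 with a peak or trough at E11.5, and 1194 and 940 with a peak or trough at E12.5. In 5 simulations of unchanged stages no gene entered any class. Those simulations held no gene that changed at only 1 step, so they do not bound the false members of a class. The 3 libraries of a stage cannot be divided into groups of at least 2, so the effect of libraries shared by successive steps could not be measured. The middle stage enters those steps with opposite sign, so its spread can add peaks and troughs but not steady rises or falls. Part of the excess of peaks and troughs at E11.5 may thus come from the shared libraries. The excess of genes rising or falling at every step and the smaller counts at E12.5 go the other way, which argues against that source for these classes.

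Against E10.5, the palate list (16 higher and 1 lower of 21), the matrix list (28 of 29 higher) and the Lin28 programme (15 of 16 lower, 1 higher) passed at E12.5. The osteoblast list (21 of 21 higher), the matrix list (29 of 29) and the Lin28 programme (15 of 16 lower) passed at E14.5. Each had adjusted p = 0.0370 with an estimated correlation, and none passed with replicate number as a block (adjusted p = 0.0597 to 0.0857). At E12.5 5147 genes were higher and 4677 lower than at E10.5, and at E14.5 6721 and 6211. Against only E10.5 replicate 3, the library of that stage whose share of alignments outside genes resembled later stages, 3126 were higher and 3072 lower at E12.5, and 5052 and 5169 at E14.5. With 1 library for E10.5 the spread comes wholly from the other stages, and fewer libraries alone can lower these counts. No list passed at E12.5 without E10.5 replicate 2, E10.5 replicate 3 or E12.5 replicate 3, or at E14.5 without E10.5 replicate 2 or 3. Without E14.5 replicate 3 only 1 passed.

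**Figure D4:**
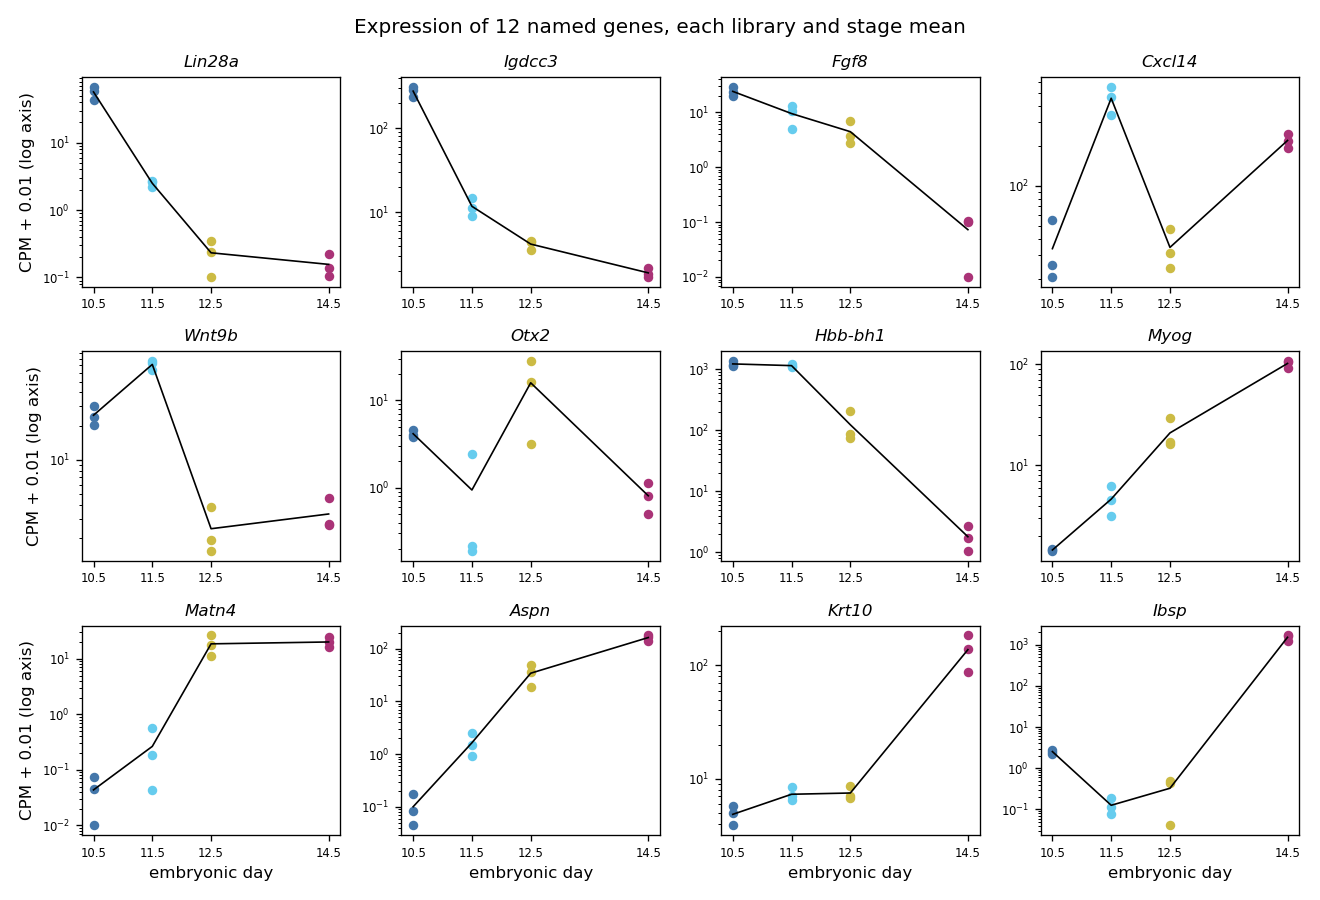
Expression of 12 genes in CPM plus 0.01 (vertical log axis) against embryonic day (horizontal axis), with a point for each of 3 libraries per stage and a line through the stage means. Lin28a and Fgf8 decline at each stage mean, Cxcl14 stands highest at E11.5, Otx2 at E12.5 and Ibsp at E14.5, where it reaches 1506 CPM.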

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

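The test with the share of alignments outside genes as a covariate was chosen only after that share had been seen. The share was 2.67%, 1.92% and 4.88% in E10.5 replicates 1, 2 and 3, 2.16%, 2.30% and 2.42% in those of E11.5, 5.03%, 5.43% and 5.25% in those of E12.5, and 6.21%, 5.78% and 5.90% in those of E14.5. It rose between E11.5 and E12.5, the step at which 1981 protein-coding and 673 noncoding genes rose at least 2-fold against 297 and 70 that fell as far.

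Genomic DNA in the E12.5 libraries would raise genes that the tissue does not use as well. Olfactory and vomeronasal receptor genes rose by 0.00240 CPM per kb. They stood at 0.00114, 0.00593 and 0.00307 in E12.5 replicates 1, 2 and 3. The rise thus came mainly from replicates 2 and 3 and did not follow the even share outside genes. Of the olfactory markers, Fezf1 (0.249, 13.7 and 6.01 CPM) and Sp8 (1.995, 18.3 and 11.76 CPM) stood in the same order, while others, such as Ebf2 and Gng8, did not. Olfactory transcripts may be part of the receptor rise, which need not measure background alone. By comparison, the rising genes rose by a median of 0.464 (protein-coding) and 0.305 (noncoding). In both classes 100% rose by more than 2 times the receptor rise. That share was nearly assured, because the genes had been picked for a 2-fold rise above a minimum count, so it decides nothing. The sizes show something narrower: a background as large as the receptor rise would be far too small for the median rises. More unspliced or nuclear RNA may explain part of the rise: with the covariate 14.4% of the protein-coding and 1.78% of the noncoding genes kept their call and a 2-fold rise. The median log2 fold change went from 1.79 to 1.40 (protein-coding) and from 1.89 to 0.74 (noncoding). The bound set for this explanation before that test was run, under 50% kept, was met in both classes. Without E10.5 replicate 3, 0.101% (protein-coding) and 0% (noncoding) kept both. The bound does not decide, because the covariate nearly follows stage. The median standard error grew from 0.35 to 0.69 (protein-coding) and from 0.48 to 0.83 (noncoding). Both are over a limit of 1.5 times, which was not part of the written bound, so genes would lose calls under either explanation. In the noncoding genes the median change itself fell below 2-fold, so the wider spread is not the only reason for their losses.

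Nuclear RNA and development therefore cannot be told apart at this step, since no E11.5 library has a high share and no E12.5 library a low one. Malat1 and Neat1, transcripts retained in the nucleus and picked after their values were seen, rose at this step, Malat1 from 55.9 ± 14.8 to 222.4 ± 46.2 CPM and Neat1 from 1.11 ± 0.22 to 6.65 ± 1.08 CPM. At E14.5, where the share was highest, Malat1 stood lower, at 159.6 ± 10.4 CPM (adjusted p = 0.262), and Neat1 higher, at 20.6 ± 2.7 CPM. In E10.5 replicates 1, 2 and 3 Malat1 measured 62.7, 34.3 and 125.9 CPM and Neat1 1.75, 1.07 and 2.93 CPM. E10.5 replicate 3, the only early library with a high share, stood above its stage by a median of 0.215 on the log2 scale in the rising protein-coding genes and 0.87 in the noncoding ones, against -0.002 and 0.33 in all genes of those classes.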

How the results depend on the processing

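The covariate fits, the use of E10.5 replicate 3 alone and the likelihood ratio test in DESeq2 were chosen only after the results had been seen. Counts of genes held within 1.5 times under other scalings, filters and tests. Calls of lists held with the size factors of DESeq2 but moved with other set tests, the block fit or a library left out. Requiring at least a 2-fold change left 904 higher and 732 lower genes from E10.5 to E11.5, 2772 and 410 from E11.5 to E12.5, 2033 and 1036 from E12.5 to E14.5, 2778 and 768 for E12.5 against E10.5, 4400 and 2310 for E14.5 against E10.5, and 8499 differing among the 4 stages. It left 70 genes rising and 6 falling at every step, 144 and 364 with a peak or trough at E11.5, and 229 and 139 with a peak or trough at E12.5. In the order E11.5 against E10.5, E12.5 against E11.5, E14.5 against E12.5, E12.5 against E10.5 and E14.5 against E10.5, lists called numbered 16, 18, 18, 17 and 19 with camera's preset correlation, 15, 21, 22, 23 and 26 with fry, and 29, 29, 31, 30 and 31 with its mixed test. With 1 library left out, lists called ranged from 0 to 5, 0 to 1, 0 to 3, 0 to 4 and 0 to 3 in that order, genes lower from E10.5 to E11.5 from 1486 to 2042, genes falling at every step from 137 to 354, and genes with a trough at E11.5 from 470 to 908.

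With replicate number as a block, no list passed in camera with an estimated correlation: 0 for E11.5 against E10.5, 0 for E14.5 against E12.5, 0 for E12.5 against E10.5 and 0 for E14.5 against E10.5. Counts of genes moved little in the block fit, with 2291 higher and 2396 lower from E10.5 to E11.5. The numbers gave no clear sign of pairing the libraries. Residuals of libraries with the same number correlated at -0.119 to 0.177 (median 0.022), with 4 of 18 pairs over a threshold of 0.1. The 36 pairs with different numbers lay at -0.228 to 0.228. Of 12 libraries 6 were closest to one with their own number, so pairing cannot be excluded.

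The share of alignments outside genes as a covariate, added after the data were seen, left 407 higher and 286 lower genes from E11.5 to E12.5, 2754 and 2861 for E12.5 against E10.5, and 3576 and 3908 for E14.5 against E10.5. It left 54 rising and 29 falling at every step, 93 and 102 with a peak or trough at E11.5, and 78 and 100 with a peak or trough at E12.5. From E11.5 to E12.5 it turned the sign for Cav3 (-0.185), Krt5 (0.39), Hbb-bs (-0.72), Aldh1a2 (-0.13) and Egr3 (-0.13), in log2. With only E10.5 replicate 3 for E10.5, 3126 genes were higher and 3072 lower at E12.5, with the spread taken wholly from the other stages. The calls of Afp, Fezf1 and Elavl3 from E11.5 to E12.5 and of Aspn from E10.5 to E11.5 were lost with limma-voom.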

Other observations

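Of the tests below, those of pool size and its cut, of mandibular, brain and olfactory markers, and of all marker lists with an estimated correlation were chosen only after the results they address had been seen. Signalling genes not described above also changed from stage to stage. Aldh1a2, which makes retinoic acid, and Cyp26b1, which degrades it, both rose from E10.5 to E11.5, from 6.06 ± 3.34 to 69.8 ± 10.1 CPM and from 8.48 ± 0.99 to 110.3 ± 8.8 CPM, and Cyp26a1 fell from E12.5 to E14.5, from 16.6 ± 2.1 to 3.76 ± 0.19 CPM. The BMP antagonists Fst and Grem1 rose from 2.39 ± 1.21 to 21.02 ± 0.49 CPM and from 2.52 ± 1.06 to 19.1 ± 0.8 CPM from E10.5 to E11.5, where 14 of 23 BMP and TGF-beta genes were higher and 3 lower (list adjusted p = 0.0680 with an estimated correlation). Hhip, a target and inhibitor of Hedgehog signalling, fell from 8.55 ± 3.77 to 2.26 ± 0.34 CPM and then rose to 18.1 ± 3.9 CPM at E12.5, and Foxl1 fell from 23.7 ± 5.5 to 1.34 ± 0.27 CPM at E14.5.

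Imprinted growth genes were higher in 11 of 20 cases from E11.5 to E12.5 and lower in none (list adjusted p = 0.191). With the share of alignments outside genes as a covariate 4 were higher. Meg3 rose from 8.15 ± 0.83 to 70.5 ± 6.1 CPM and the zinc finger gene Plagl1 from 85.6 ± 1.7 to 355.1 ± 7.3 CPM. In E10.5 replicates 1, 2 and 3 Meg3 measured 11.2, 7.13 and 23.4 CPM, highest in the early library with a high share. From E12.5 to E14.5 Dlk1 rose from 128.1 ± 13.2 to 451.5 ± 46.6 CPM and Nnat fell from 784.7 ± 131.2 to 176.1 ± 5.3 CPM. Of 18 neural crest factors 5 were higher and 9 lower from E11.5 to E12.5 (list adjusted p = 0.348), and 3 and 5 with that covariate. Ednrb rose from 18.0 ± 2.9 to 58.3 ± 13.5 CPM, while Tfap2a and Pax3 fell, from 38.0 ± 3.6 to 11.7 ± 0.4 CPM and from 75.0 ± 3.5 to 10.1 ± 5.7 CPM. Acta2, the smooth muscle actin, rose at the later steps, from 10.8 ± 0.5 to 53.6 ± 18.95 and 244.6 ± 18.3 CPM, and so did the potassium channel of pericytes Kcnj8, from 0.142 ± 0.189 to 1.90 ± 0.32 and 8.15 ± 1.80 CPM. The growth-response gene Egr1 rose from 5.83 ± 1.27 to 31.4 ± 0.6 CPM and Fos from 1.16 ± 0.45 to 8.01 ± 1.47 CPM at E14.5.

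By a cut at 1% of the highest library, 3 of 12 libraries carried RNA of mainly 1 sex: E10.5 replicate 2 and E12.5 replicate 2 with Xist at 0.0739 and 9.38 CPM, and E14.5 replicate 1 with no Y-linked count. E12.5 replicate 2 may hold a little female RNA, and a cut at 0.1%, set after these values were seen, leaves 2 libraries (exact p = 0.0145 for pools of 7). If every library pooled 7 littermates of random sex, 0.188 such libraries would be expected (exact p = 0.000755), so pools of that size in equal parts do not account for them. Pools of 3 would give 3.00 (exact p = 1), but that size was chosen after the count was known, and single embryos in some libraries or unequal amounts of tissue cannot be told apart from it.

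Hand2, Ret, Dbh and Tlx2, which are active in autonomic neurons, were all higher at E12.5 than at E11.5. Of a list of other autonomic markers 61.5% were higher (8 of 13 tested, with 1, Gata3, lower). Among random lists matched on expression 7.13% reached that share, so the bound written before this test was missed. Mandibular markers were higher in 33.3% of cases (67.3% of random lists). Brain markers were higher in 85.7% of cases (6 of 7 tested, 1.72% of random lists), with Emx2 lower. Of the higher ones, Six6 and Sox1 averaged only 0.407 and 0.333 CPM at E12.5. Olfactory markers were higher in 61.5% (8 of 13 tested, 2 lower, 2.94% of random lists). Both shares met bounds that were set only after the rises had been seen. Random lists ignore correlation between genes, and all 10 brain markers belong to the list whose rise prompted the test. With an estimated correlation none of the 4 marker lists passed (adjusted p = 0.217, 0.869, 0.579 and 0.217 in that order). Some genes of either kind differed among E12.5 replicates 1, 2 and 3, such as Lhx2 (0.842, 39.7 and 23.2 CPM), Fezf1 (0.249, 13.7 and 6.01 CPM) and Dbh (1.65, 8.03 and 5.75 CPM). Others were even, such as Ebf2 (48.1, 54.0 and 65.7 CPM) and Gng8 (7.36, 7.88 and 6.65 CPM), so neighbouring tissue and a change within the prominence cannot be told apart.

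With 10 splits of the 6 libraries of a comparison, splits are too few for a share under 0.05. The real grouping gave 4615 called genes from E10.5 to E11.5 (highest other split 0), 9047 from E11.5 to E12.5 (1), 8646 from E12.5 to E14.5 (0), 9824 for E12.5 against E10.5 (0) and 12932 for E14.5 against E10.5 (0), each the first of its splits (1 of 10). Lists gave 3 (highest other 0), 0 (0, all 10 alike), 1 (0), 3 (1) and 3 (0) in that order. Of 100 splits of all 12 libraries, only the real one (1 of 100) reached 14995 genes differing among stages (highest other 6346), 320 rising (0) and 254 falling (0) at every step, 639 with a peak (16) and 555 with a trough (8) at E12.5. For 512 genes with a peak and 788 with a trough at E11.5, 2 of 100 did, with 2162 and 2608 in the split that keeps the E14.5 libraries together in the place of E11.5. All other splits, of 6 or of 12 libraries, put libraries of different stages into a group, which widens the spread there. The ranks of the real grouping therefore follow from the stage differences themselves and are no separate evidence for any class.

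Ibsp had a level of 2.53 ± 0.26 CPM at E10.5, above 0.116 ± 0.056 CPM at E11.5, before its rise at E14.5. Apoa1, like Afp a plasma protein gene, was highest at E12.5 (1.70 ± 1.94 CPM). As for Afp, that mean came mainly from replicate 1 (3.93, 0.794 and 0.378 CPM in replicates 1, 2 and 3). Hoxa2, a gene of the hindbrain and second arch, averaged 0.626 ± 1.026 CPM at E10.5 and 1.10 ± 1.47 CPM at E14.5, mainly from 1 library at each stage, while E12.5 libraries were even (0.561, 0.458 and 0.581 CPM).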
